A study of Rattus norvegicus with 18 samples.

How the data were processed

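Liver RNA from 12-week-old Sprague-Dawley rats was measured on 18 Affymetrix Rat Genome 230 2.0 arrays, 3 in each of 6 groups. Per the labels, the tissue came from the middle of the right lobe after blood had been removed through the portal vein, RNA was extracted with Trizol and RNeasy columns, and 5 ug of RNA was used per array. The groups were normal liver (0 h), sham operation (2 h), partial hepatectomy (PH, 2 h), sympathectomy with PH (SPH, 2 h), vagotomy with PH (VPH, 2 h) and total liver denervation with PH (TDPH, 2 h). The labels call the arrays of a group technical replicates. All p-values and SDs therefore measure the spread between arrays only, n counts arrays and not animals, and the number of animals behind a group is not given in the sources used here.

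The deposited value table holds a signal intensity for each of 31099 probe sets on each array, on a linear scale. GCOS 2.0 is named for these signals in the submitters' processing notes. On every array the mean signal without the lowest and highest 2% of probe sets was 500, so each array had been scaled to a common trimmed mean. The method of background subtraction is not given in the sources used here. The deposited files used here hold no detection calls. A second deposited table holds signals, log2 ratios and linear ratios for the same groups, per the file headers. Its log2 ratios, in steps of 0.1, set each array of a 2 h group against each array of normal liver, and its ratio columns equal 2 to the power of those log2 values; how the authors computed them is not given in the sources used here. Across 12740 probe sets these deposited log2 ratios, averaged per group, correlated with the differences of log2 signal at r = 0.952 (sham) to 0.973 (SPH), a correlation across genes, which are not independent replicates. Of its 18 signal columns, 17 equal an array of the value table within 0.06 for 31042 of 31042 probe sets. The first column under its VPH heading equals no array (65 of 31042 probe sets equal), and VPH replicate 3 of the value table is not among its columns.

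Signals were used as deposited, without further normalization, as log2(signal + 12), where 12 is the 10th percentile of all signals. Differences are on this scale, which understates changes of dim probe sets. The 57 control probe sets were left out, and 22103 probe sets above the 40th percentile of their array on at least 3 arrays were tested. Group means were fitted to all 18 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend on the mean level), with 12 residual degrees of freedom and 7.1 from the prior. Tests were two-sided, with Benjamini-Hochberg adjustment within each comparison. A probe set was called changed at an adjusted p under 0.05 and a difference of at least 2-fold, and "rose" and "fell" refer to such calls alone. Of the comparisons, 5 were set as primary before the data were examined (PH with sham, sham with normal, and SPH, VPH and TDPH each with PH). The 3 denervated groups were also compared directly, and the non-additivity contrast TDPH - SPH - VPH + PH was tested.

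Gene names came from the platform annotation, brought to current symbols through a rat gene table. Of the 31099 probe sets, 19914 had 1 symbol, 343 several and 10842 none. Of those with 1 symbol, 16015 were current, 2401 were updated through a synonym and 158 through an accession, while 20 whose accession names another gene and 26 with a number in place of a symbol were left unnamed. Probe sets with several symbols named no gene. Each gene was represented by the probe set with the highest mean log2 signal over all arrays among those naming it alone, which gave 11480 tested genes, and for some named genes other probe sets are given as well. Positions in the genome were not analysed here. The RT1 genes of the rat MHC, Obp3 and RatNP-3b belong to multigene families, and the probe set of Jun is marked as able to bind more than a single transcript, so their signals may mix family members or transcripts.

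In all, 33 gene lists of pathways and cell types were fixed before the data were examined. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the 33 lists. Without further words, a list's adjusted p is that of camera at the preset correlation; of 75 lists called in the primary comparisons, 29 were also called with an estimated correlation. Counts of members are given over all probe sets tested and adjusted over the list alone. Genes are named by a rule fixed in advance. For each primary comparison it takes the 8 largest rises and 8 largest falls among called genes whose 3 arrays of a group all lie beyond the 3 of the other, the 12 list members with the largest absolute difference among such genes, and 19 fixed genes whether called or not. Il6, a fixed gene, did not pass the filter. Some genes that the rule takes are not reported here. For each direct comparison and for the non-additivity contrast it takes the 5 largest rises and falls. The condition on non-overlapping arrays was not defined for the non-additivity contrast and was not applied there. Groups of 3 arrays fail to overlap by chance in 10% of probe sets. List members given as examples beyond this rule were chosen after their values were seen.

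The fit was tested on simulated data built from the PH and sham comparison (22103 probe sets). Of 100 probe sets changed by 1.5 on the log2 scale 80% were recovered, and of 100 changed by 2, 87%. There were 6 false calls, an unchanged comparison gave 0 calls at adjusted p under 0.05 and 2-fold, and the list that had been shifted was called with 0 of the others. The simulated probe sets varied independently, so false calls of lists with correlated genes were not tested. Alternatives set before the data were examined were quantile normalization, pseudocounts of 1 and of the 40th percentile (90), no filter, no mean-variance trend, array weights, a fit of only the groups compared, the replicate number as a block, adjusted p without a fold minimum, a 3-fold minimum, the 2-fold rule without a test, the signals of the second table, and each array left out in turn. Centring each array on its median and averaging VPH replicates 2 and 3 were added after seeing the data, as was the second table for the gene lists.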

Results

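Gene expression was measured in the rat liver 2 h after part of it had been removed (partial hepatectomy, PH), an operation after which the remaining liver regrows. The nerves of the liver were left intact or cut beforehand, so that the first transcriptional response could be compared with and without them. There were 3 arrays in each of 6 groups: normal liver at 0 h, sham operation at 2 h, PH at 2 h, and PH at 2 h with sympathectomy (SPH, loss of the splanchnic sympathetic supply), with vagotomy (VPH, loss of the vagal parasympathetic supply) or with total liver denervation (TDPH). The trimmed mean signal was 500 on all 18 arrays. Median signal was lowest after PH (124.3 ± 8.18, SD, n = 3) and highest in normal liver (147.1 ± 3.7). The ratio of 3' to 5' Actb signal, a measure of RNA integrity, was 1.89 in normal liver, 2.19 after sham operation, 1.76 after PH, 1.8 in SPH, 1.84 in VPH and 2.0 in TDPH, and that of Gapdh was 1.29, 1.35, 1.21, 1.29, 1.18 and 1.3 in the same order. No group was denervated without PH, so a difference between a denervated group and PH cannot be divided into a changed response to PH and an effect of the denervation operation itself. The number of arrays limits the precision of every value.

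Sham operation at 2 h was compared with normal liver at 0 h to find genes that respond to the operation. No group was left unoperated until 2 h, so the operation cannot be told apart from the elapsed time and whatever else changed with it. Genes induced by glucocorticoids, the adrenal stress hormones, were higher as a list at 2 h, and lymphocyte markers were lower as a list. Mt2A, a metal-binding metallothionein, rose from 2370 ± 310 to 22400 ± 640 (signal, mean ± SD, n = 3; log2 difference 3.24, SE 0.08, adjusted p = 9.27e-17). Cd74, the invariant chain of MHC class II, fell from 20400 ± 500 to 2720 ± 130 (-2.9, SE 0.23, adjusted p = 1.41e-08).

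Of 18 measured glucocorticoid response genes, 8 rose, 1 fell (Sgk1, -1.05) and 9 were not called, with the same counts of 8 and 1 adjusted over the list alone and a median log2 difference of 0.62 (adjusted p = 7.28e-13). Those that rose included Sds, a serine dehydratase that feeds gluconeogenesis (8350 ± 220 against 1690 ± 160, 2.3), Mt1 (2.23), Fkbp5 (1.66) and the cell-cycle inhibitor Cdkn1a (1.42). Another probe set of Mt1 was at 1.14. Igfbp1, which binds insulin-like growth factors, rose from 10300 ± 160 to 23200 ± 570 (1.17). Of the lists of liver metabolism, several were higher by smaller amounts, while fatty acid synthesis was lower (1 of 18 fell, the same over the list alone; median -0.22, adjusted p = 0.022, and adjusted p = 0.429 with an estimated correlation or 0.0554 with centred arrays). Among 27 genes of gluconeogenesis and glycogen, 4 rose (4 adjusted over the list alone; median 0.3, adjusted p = 9.06e-09), including the coactivator Ppargc1a (1.57). Of 25 genes of fatty acid oxidation, 2 rose (2 adjusted over the list alone; median 0.32, adjusted p = 5e-12), namely Cpt1a, the entry enzyme of mitochondrial oxidation (2.09), and Angptl4 (1.32). In the drug metabolism list 3 of 31 rose (3 adjusted over the list alone; median 0.31, adjusted p = 3.46e-13), led by Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor (683 ± 67 against 23.7 ± 6.8, 4.29, SE 0.16). In the urea cycle and amino acid list 3 of 32 rose (3 adjusted over the list alone; median 0.33, adjusted p = 3.96e-15). The IL6-STAT3 and acute phase list was also higher (median 0.24, adjusted p = 6.02e-13, and adjusted p = 0.064 with an estimated correlation), with 3 of 32 members called over all genes and over the list alone, among them the feedback inhibitor Socs3 (298 ± 45 to 718 ± 120, 1.24). Outside the lists, the protease inhibitor Serpinb9b (3.34), Duoxa1 (2.4) and the zinc finger gene Zfp354a (2.29) rose. A probe set of Dhrs7 rose by 3.43, while another of the same gene differed by 0.21.

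Of 20 lymphocyte markers, 9 fell and 11 were not called (10 fell adjusted over the list alone; median -1.01, adjusted p = 7.18e-09). Besides Cd74 they included Cd3e of the T cell receptor complex (294 ± 47 to 67.1 ± 43, -2.14) and Cd2 (-1.93). The MHC class II genes RT1-Ba (-3.21), RT1-Bb (-3.08), RT1-Da (-2.98) and RT1-Db1 (-2.96) fell with them, with other probe sets of RT1-Ba at -3.19, 0.12 and -0.3. Of 15 macrophage and Kupffer cell markers, 4 fell (4 adjusted over the list alone; median -0.62, adjusted p = 5.42e-12), among them Adgre1 (-1.53) and Aif1 (-1.32; another probe set -0.35). Endothelial markers were lower as a list (median -0.33, adjusted p = 0.0271, and adjusted p = 0.311 with an estimated correlation, 0.0583 with quantile normalization or 0.0551 without normal replicate 3), with 13 of 13 not called singly, and the neutrophil (-0.33, adjusted p = 0.115), stellate (-0.28, adjusted p = 0.111) and cholangiocyte lists (-0.27, adjusted p = 0.215) had medians below 0. Hepatocyte secreted genes were higher as a list (median 0.21, adjusted p = 4.48e-10, and adjusted p = 0.123 with an estimated correlation or 0.898 with quantile normalization), with 22 of 22 not called singly. In the NF-kB and cytokine list 7 of 26 fell and 2 rose (7 and 2 adjusted over the list alone; median -0.67, adjusted p = 0.000324, and adjusted p = 0.116 with an estimated correlation). The adhesion molecule Vcam1 fell by 2.18 there, while the neutrophil chemokine Cxcl1 rose from 1590 ± 19 to 13000 ± 200 (3.02). Gbp2, a guanylate-binding protein induced by interferon, fell from 2790 ± 160 to 388 ± 76 (-2.83), and the interferon response list was lower (4 of 29 fell and 1 rose, the same over the list alone; median -0.18, adjusted p = 0.000327, and adjusted p = 0.221 with an estimated correlation). Other falls were those of the growth factors Gdf15 (-2.35) and Tgfb1 (-2.34), of Evl (-2.86; another probe set 0.25) and of the stress transcription factor Atf3 (-1.48). Cpa1, a digestive carboxypeptidase of the pancreas, fell from 2260 ± 430 to 193 ± 34 (-3.47), while the list of 11 pancreas markers had a median of -0.13 (adjusted p = 0.15). Red cell markers had a median of 0.17 and a mean of 0.64 (adjusted p = 0.022, and adjusted p = 0.064 with an estimated correlation), with Hbb at 1.73. Among the fixed genes, Jun (-0.85), Ccnd1 (-0.61), Egr1 (-0.59), G6pc1 (0.6), Cyp7a1 (0.45) and Pck1 (0.41) had adjusted p of 7.92e-05 or lower and stayed under 2-fold. Alb (0.23), Fos (-0.27), Adra1b (0.01), Tnf (-1.05), Chrm3 (0.07) and Hgf (-0.1) did not pass the test, nor did Myc, at -0.04 with the deposited scaling and 0.07 with centred arrays.

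In limma's test 227 probe sets were higher and 440 lower after sham operation than in normal liver (104 and 260 genes). The split was 311 and 322 with arrays centred on their median. With a pseudocount of 90 the differences of Atf3 and Ppargc1a were -0.89 and 0.68, under 2-fold, and that of Ppargc1a had an adjusted p = 0.0835 when only these groups were fitted.

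PH was compared with sham operation to separate the response to lost liver tissue from that to the operation. Immediate early genes, which are transcribed without new protein synthesis, had the highest median difference of all lists. Nr4a1, an orphan nuclear receptor induced by cAMP and stress, went from 106 ± 38 to 2740 ± 140 (signal, mean ± SD, n = 3; log2 difference 4.6, SE 0.21, adjusted p = 2.58e-12). Btg2, which restrains proliferation, reached 19700 ± 560 from 2600 ± 49 (2.92, SE 0.05, adjusted p = 2.18e-18). Ppp1r3c, which directs protein phosphatase 1 to glycogen, fell from 4020 ± 190 to 810 ± 100 (-2.3, SE 0.16, adjusted p = 2.6e-09).

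Of 37 immediate early genes, 21 rose and 16 were not called (21 rose adjusted over the list alone; median 1.25, adjusted p = 4.85e-28). The transcription factors Maff (642 ± 72 against 19.1 ± 8.2, 4.42), Atf3 (3.24), Fosl2 (2.87), Fos (2470 ± 61 against 398 ± 67, 2.61), Myc (2000 ± 120 against 325 ± 35, 2.58) and Egr1 (16400 ± 500 against 3680 ± 8.1, 2.15) were among them. Jun differed by 0.93 (adjusted p = 1.22e-10), under 2-fold, while others of its probe sets were at 1.33, a rise, and 0.87. The cAMP response list, which shares Nr4a1 and Fos, had 8 of 18 members higher (8 adjusted over the list alone; median 0.96, adjusted p = 6.27e-12), including Igfbp1 (1.03), Sik1 (1.59) and Ppargc1a (1.46). Growth factor and receptor genes had 8 of 34 higher and 1 lower (9 and 1 adjusted over the list alone; median 0.29, adjusted p = 0.00263), among them the matricellular genes Ccn1 (648 ± 1.8 against 79 ± 11, 2.87) and Ccn2 (2.3).

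In the NF-kB and cytokine list 8 of 26 rose (8 adjusted over the list alone; median 0.75, adjusted p = 2.35e-11), including the chemokines Ccl2, which attracts monocytes (209 ± 13 against 13.5 ± 6.5, 3.15), and Cxcl2, which attracts neutrophils (609 ± 100 against 66.5 ± 14, 2.98). Of 32 IL6-STAT3 and acute phase genes, 6 rose (6 adjusted over the list alone; median 0.34, adjusted p = 2.13e-15), among them Lcn2, a siderophore-binding lipocalin (1060 ± 120 against 81.7 ± 11, 3.52), the protease inhibitor A2m (6270 ± 280 against 894 ± 110, 2.8) and the interleukin-1 receptor antagonist Il1rn (2.79). Neutrophil markers had 5 of 9 higher (5 adjusted over the list alone; median 1.17, adjusted p = 1.07e-05, and adjusted p = 0.0549 with an estimated correlation), with S100a9 at 2.74 and S100a8 at 2.64. Stellate cell and fibroblast markers had 4 of 17 higher (4 adjusted over the list alone; median 0.46, adjusted p = 0.00506), such as Vim (1.62) and Acta2 (1.29). Of 20 lymphocyte markers 4 rose (4 adjusted over the list alone; median 0.38, adjusted p = 0.00999, and adjusted p = 0.143 with an estimated correlation). Macrophage markers were higher as a list (median 0.35, adjusted p = 1.27e-05), with 15 of 15 not called singly. Outside the lists, Tnfrsf12a, the receptor of the cytokine TWEAK (4.28), the hyaluronidase Cemip2 (4.17), Rgs1, which shortens G protein signals (3.82), the prostacyclin synthase Ptgis (3.8) and the small GTPase Gem (3.3) rose.

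Among lowered genes was Ppp1r3b, a second glycogen-targeting subunit (-2.25), while the gluconeogenesis and glycogen list as a whole had 2 higher, 2 lower and a median of 0.07 (2 and 2 adjusted over the list alone; adjusted p = 0.196). G0s2, an inhibitor of triglyceride lipase, fell from 8180 ± 87 to 1490 ± 47 (-2.45). Serpinb9b fell from 924 ± 43 to 35 ± 24 (-4.42), and Rtp3 (-2.33), Coa4, which takes part in the assembly of cytochrome oxidase (-2.33), the zinc finger gene Zfp37 (-2.4) and the androgen-regulated Pbsn (-2.55) also fell. The replication helicase Dna2 (-2.63) was lower. Of 28 genes of S phase and mitosis, 5 fell (5 adjusted over the list alone; median -0.78, adjusted p = 0.00109, and adjusted p = 0.165 with an estimated correlation), including the mitotic kinases Plk1 (-1.59) and Aurka (-1.49). Ccnd1, the cyclin of the G1 phase, differed by 0.56 (adjusted p = 0.000161), Socs3 by 0.51, Adra1b by -0.54, G6pc1 by -0.65 and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, by -0.88 (adjusted p = 5.64e-11), all under 2-fold. Chrm3 (-1.01), Tnf (0.77) and Hgf (0.32) did not pass the test. Pck1 and Alb did not either, at -0.04 and -0.02 with the deposited scaling and 0.11 and 0.13 with centred arrays.

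After PH 438 probe sets were higher and 525 lower than after sham operation (252 and 219 genes). The median over all tested probe sets was -0.113. The split was 556 and 332 with quantile normalization and 628 and 310 with centred arrays. Under quantile normalization Igfbp1 differed by 0.96, and with a pseudocount of 90 Ppargc1a differed by 0.97, each under 2-fold.

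**Figure D1:**
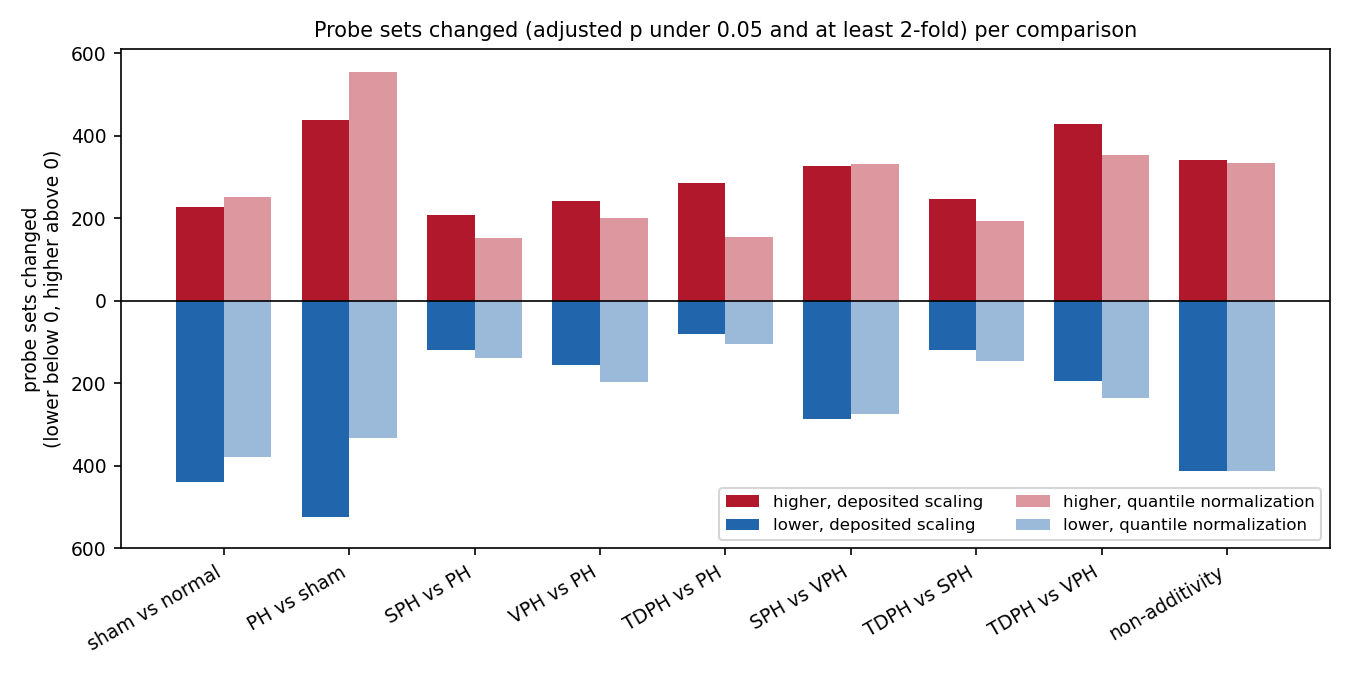
Number of probe sets changed in each comparison (vertical axis, higher above 0 and lower below it), with the deposited scaling and after quantile normalization as separate bars. In PH against sham the bars are 438 and 525 with the deposited scaling and 556 and 332 after quantile normalization.

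SPH was compared with PH to find the genes that differ 2 h after PH when the sympathetic supply has been cut. Nr4a1 and 6 of 9 neutrophil markers were higher with sympathectomy, and the genes Ppp1r3c, A2m and Cpa1 were lower. The neutrophil list had an adjusted p = 0.0507 with an estimated correlation. Nr4a1 reached 8540 ± 1100 in SPH against 2740 ± 140 in PH (n = 3; log2 difference 1.63, SE 0.21, adjusted p = 2.52e-05). The glycogen-targeting Ppp1r3c was at 258 ± 110 against 810 ± 100 (-1.67, SE 0.16, adjusted p = 1.38e-06), while another of its probe sets differed by -0.51. The acute phase gene A2m was at 2100 ± 660 against 6270 ± 280 (-1.62, SE 0.14), while the IL6-STAT3 and acute phase list was higher as a whole (1 of 32 fell, the same over the list alone; median 0.17, adjusted p = 0.000225, and adjusted p = 0.276 with an estimated correlation or 0.238 with quantile normalization).

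Of 9 neutrophil markers, 6 rose and 3 were not called (8 rose adjusted over the list alone; median 1.12, adjusted p = 7.59e-06, and adjusted p = 0.0507 with an estimated correlation). The neutrophil collagenase Mmp8 (738 ± 290 against 258 ± 31, 1.41), S100a9 (1.22) and S100a8 (1.12) were among them. S100a8 signal was 12100, 7700 and 5440 on the 3 SPH arrays. In all comparisons with SPH the adjusted p of single genes uses a spread pooled over all groups. Among 29 interferon response genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone; median 0.28, adjusted p = 2.73e-06, and adjusted p = 0.123 with an estimated correlation), with Ifit3 at 1.64, Isg15 at 1.21 and Mx1 at 1.18. The gene that fell was Mx2 (-1.16), while another of its probe sets rose by 1.85. Macrophage markers were higher as a list (median 0.24, adjusted p = 8.76e-07), with 15 of 15 not called singly. The cAMP response list was higher (median 0.19, adjusted p = 0.000702), with Nr4a1 the 1 member of 18 to rise (1 adjusted over the list alone). Of the immediate early genes, Nr4a1 alone was called, while Egr1 (0.29) and Jun (-0.41) stayed under 2-fold and Fos (-0.27), Myc (-0.01) and Atf3 (0.32) did not pass the test. The whole list had a median of 0.18 (adjusted p = 0.00224, and adjusted p = 0.123 with an estimated correlation), and without SPH replicate 1 its median was 0.14 (adjusted p = 0.0634).

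Other genes that rose were Prkcz, an atypical protein kinase C (2.19), the TGF-beta receptor Tgfbr2 (238 ± 11 against 48.4 ± 30, 2.16), the potassium channel Kcnh1 (2.31), the secreted phospholipase Pla2g2d (2.0), the MHC class I gene RT1-T24-3 (2.13) and Gpam, which starts glycerolipid synthesis (1930 ± 400 against 718 ± 12, 1.39). Genes that fell were the neurotrophin Ntf3 (-2.16), the uncoupling protein Ucp1 (-2.31), the aldo-keto reductase Akr1b7 (-1.78), Fbxl8 (-1.78) and the pancreatic carboxypeptidase Cpa1 (33.5 ± 16 against 144 ± 37, -1.82). The pancreas list had 2 of 11 lower (2 adjusted over the list alone) and a median of -0.08 (adjusted p = 0.175). Akr1b7 signal was 5690, 1860 and 821 on the SPH arrays. Cyp7a1 was at 9800 ± 660 against 5470 ± 220 (0.84, adjusted p = 9.45e-09), under 2-fold, as were Socs3 (0.6), Alb (0.38), Igfbp1 (0.26) and Pck1 (0.2). Ppargc1a (0.74), Hgf (1.12), Chrm3 (0.82), Adra1b (0.23), Ccnd1 (0.05) and Tnf (-0.12) did not pass the test, nor did G6pc1, at 0.06 with the deposited scaling and -0.01 with centred arrays.

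In SPH 208 probe sets were higher and 120 lower than in PH (99 and 42 genes); the split was 153 and 138 with quantile normalization and 152 and 152 with centred arrays, and 168 probe sets were called when only these groups were fitted. Tmem117, Fst, Mthfd2, Cxcr2 and Pfkfb3 also rose, but leaving out a single array ended each call, with the highest adjusted p at 0.125 (without PH replicate 2), 0.0634 (without SPH replicate 2), 0.12 (without SPH replicate 3), 0.203 (without SPH replicate 1) and 0.228 (without PH replicate 1) respectively, and another probe set of Pfkfb3 was at -0.88 (adjusted p = 0.433). The calls of Kcnh1, Ntf3, Akr1b7, Ucp1 and Fbxl8 ended when only these groups were fitted (adjusted p from 0.0519 to 0.138), and that of Cpa1 with a pseudocount of 90 (-0.92).

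VPH was compared with PH to find the genes that differ 2 h after PH when the vagal supply has been cut. Lymphocyte, macrophage and interferon response genes were higher as lists after vagotomy, and immediate early genes were lower as a list. Cxcl9, a T cell chemokine induced by interferon gamma, was at 5740 ± 210 in VPH and 993 ± 21 in PH (n = 3; log2 difference 2.52, SE 0.15, adjusted p = 1.72e-09). Cxcl2 was at 121 ± 12 against 609 ± 100 (-2.21, SE 0.27, adjusted p = 1.54e-05). Lcn2 was at 6510 ± 55 against 1060 ± 120 (2.61, SE 0.41, adjusted p = 0.000187).

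Of 20 lymphocyte markers, 7 rose and 13 were not called (8 rose adjusted over the list alone; median 0.95, adjusted p = 2.72e-08). They were Cd8a of cytotoxic T cells (214 ± 27 against 71 ± 26, 1.48), Cd74 (1.46), the natural killer receptor Klrd1 (1.3), the cytotoxic granule genes Prf1 (1.24), Gzmb (1.17; other probe sets 1.21 and 0.54) and Gzma (1.11), and Nkg7 (1.14). Of 29 interferon response genes, 8 rose (8 adjusted over the list alone; median 0.49, adjusted p = 3.99e-12), including Gbp2 (2890 ± 190 against 953 ± 9.7, 1.59), Isg15 (1.46), Mx1 (1.46) and the proteasome subunit Psmb9 (1.29). Macrophage markers were higher as a list (median 0.56, adjusted p = 1.31e-13), with 15 of 15 not called singly. The red cell list had a median of 0.31 (adjusted p = 0.541), the endothelial list -0.25 (adjusted p = 0.0388, and adjusted p = 0.337 with an estimated correlation) and the stellate list -0.25 (adjusted p = 0.133). Of 28 S phase and mitosis genes, 4 rose (5 adjusted over the list alone; median 0.57, adjusted p = 2.98e-05, and adjusted p = 0.0866 with an estimated correlation), with Aurka at 1.31 and Kif20a at 1.25 (another probe set 0.81, adjusted p = 0.346).

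Immediate early genes were lower as a list (1 of 37 rose and 2 fell, the same over the list alone; median -0.2, adjusted p = 3.11e-05). Fosl2 fell (111 ± 26 against 399 ± 97, -1.74), as did Maff (-1.2), while Irf1, which is also an interferon response gene, rose (1.09). Fos (-0.83, adjusted p = 5.06e-06), Jun (-0.53), Myc (-0.5), Egr1 (-0.46) and Igfbp1 (-0.45) stayed under 2-fold, and Atf3 (-0.54) did not pass the test. The fatty acid oxidation list was lower (2 of 25 fell, the same over the list alone; median -0.19, adjusted p = 3.63e-08). The genes that fell were Ppara, the fatty acid receptor that induces the pathway (-1.47), and Pdk4, which restrains glucose oxidation (-1.03). Bile acid synthesis and transport genes were lower as a list (1 of 20 fell, the same over the list alone; median -0.12, adjusted p = 0.00369), although Cyp7a1 was at 6830 ± 35 against 5470 ± 220 (0.32). Further rises were those of Pla2g2d (840 ± 69 against 60.6 ± 21, 3.59), Serpinb9b (2.82), the MHC class I gene RT1-T24-4 (2.59), Kcnh1 (2.31), the nucleotide receptor P2ry6 (2.26) and Cpa1 (2.22). The pancreas list had 2 of 11 higher, 1 lower (the same over the list alone) and a median of -0.18 (adjusted p = 0.641). Further falls were those of the collagen cross-linking oxidase Lox (-2.03), the ubiquitin-like gene Ubd (8540 ± 60 to 2170 ± 40, -1.97), the kinase gene Map2k6 (-1.95), the lipocalin Obp3 (-1.93) and the heme-regulated repressor Bach1 (-1.9). A probe set of Dhrs7 fell by 2.9, while another differed by -0.26. The remaining fixed genes did not reach 2-fold, with G6pc1 at -0.27, Ccnd1 at 0.13, Ppargc1a at 0.12, Socs3 at 0.03, Adra1b at -0.02, Pck1 at -0.07 and Hgf at 0.22. Alb was at -0.05 with the deposited scaling and 0.04 with the signals of the second deposited table. Chrm3 and Tnf were at 0.22 each, and at -0.31 without PH replicate 1 and -0.42 without PH replicate 3.

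In VPH 242 probe sets were higher and 155 lower than in PH (141 and 70 genes), with a split of 200 and 196 under quantile normalization and 192 and 220 with centred arrays. Shox2, Cpb1 and Mcm3 also rose and Stc2 also fell, but leaving out a single array ended these calls and that of Ppara, with the highest adjusted p at 0.0844 (Shox2 without PH replicate 1), 0.16 (Cpb1 without PH replicate 2), 0.105 (Mcm3 without PH replicate 1), 0.133 (Stc2 without VPH replicate 2) and 0.109 (Ppara without VPH replicate 1). Without PH replicate 1, PH replicate 3 or VPH replicate 1 the endothelial list had adjusted p of 0.0777, 0.0894 and 0.0628, and with a pseudocount of 90 the differences of Kcnh1, Bach1 and Cd8a were 0.99, -0.9 and 0.93.

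**Figure D2:**
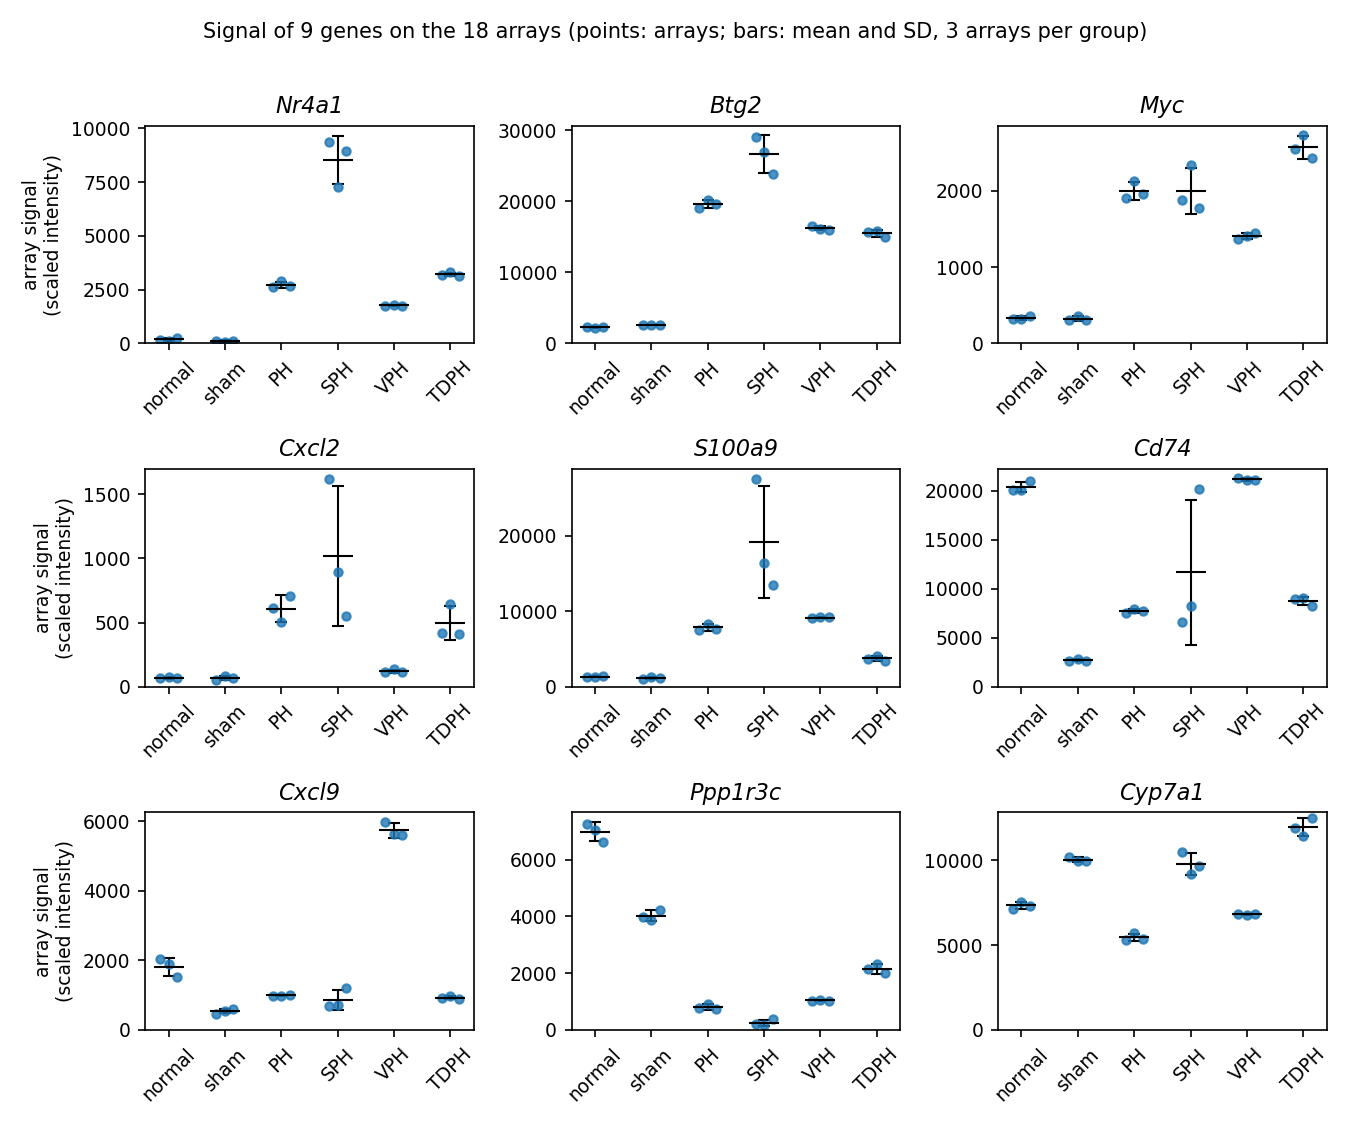
Signal (linear scale from 0) of Nr4a1, Btg2, Myc, Cxcl2, S100a9, Cd74, Cxcl9, Ppp1r3c and Cyp7a1 in the 6 groups, with a point for each of the 18 arrays and bars for the mean and SD of 3 arrays; these genes were chosen after their values were seen. Nr4a1 is at 106 ± 38 after sham operation, 2740 ± 140 after PH and 8540 ± 1100 in SPH, and Cxcl9 is at 993 ± 21 after PH and 5740 ± 210 in VPH.

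TDPH was compared with PH to find the genes that differ 2 h after PH when the whole autonomic supply has been cut. The glycogen-targeting Ppp1r3c and 5 of 29 interferon response genes were higher with total denervation, and genes of fatty acid oxidation were lower as a list. The interferon response list had an adjusted p = 0.183 with an estimated correlation. Ppp1r3c was at 2160 ± 170 in TDPH and 810 ± 100 in PH (n = 3; log2 difference 1.4, SE 0.16, adjusted p = 6.95e-06). Isg15, a ubiquitin-like protein induced by interferon, was at 2330 ± 460 against 735 ± 61 (1.63, SE 0.14, adjusted p = 2.8e-07). Serpinb9b was at 1020 ± 300 against 35 ± 24 (4.53, SE 0.32, adjusted p = 1.82e-08).

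Of 29 interferon response genes, 5 rose and 24 were not called (5 rose adjusted over the list alone; median 0.48, adjusted p = 4.54e-07, and adjusted p = 0.183 with an estimated correlation). They were Mx1 (1.79), Isg15, the interferon regulatory factor Irf7 (3110 ± 280 against 1120 ± 27, 1.46), Ifit3 (1.32) and Rsad2 (1.01). The fatty acid oxidation list was lower (median -0.3, adjusted p = 2.48e-12), with 25 of 25 members not called singly. Among 27 gluconeogenesis and glycogen genes, Ppp1r3c was the 1 to rise (2 adjusted over the list alone; median 0.21, adjusted p = 0.0389, and adjusted p = 0.183 with an estimated correlation); the list's adjusted p was 0.256 with centred arrays, 0.0938 without PH replicate 1 and 0.0512 without TDPH replicate 1. Of 9 neutrophil markers 2 fell (3 adjusted over the list alone; median -0.46, adjusted p = 0.0389, and adjusted p = 0.566 with an estimated correlation), namely S100a8 (1340 ± 170 against 3670 ± 120, -1.45) and S100a9 (-1.07); the list's adjusted p was 0.159 with centred arrays, 0.0669 without PH replicate 1, 0.0512 without TDPH replicate 1 and 0.0741 without TDPH replicate 3. Stellate cell markers had 2 of 17 lower (2 adjusted over the list alone; median -0.35, adjusted p = 0.0217, and adjusted p = 0.1 with an estimated correlation), with adjusted p = 0.0512 without TDPH replicate 1 and 0.0804 with centred arrays. A collagen gene among them, Col1a2, fell by 1.24, while another of its probe sets differed by -0.14 and the call ended without TDPH replicate 2 (-0.97). The immediate early list had a median of 0.05 (adjusted p = 0.884), with Fos at -0.93 (adjusted p = 1.28e-06), Myc at 0.36, Socs3 at 0.44, Atf3 at 0.34, Jun at -0.08 and Egr1 at -0.12, or 0.08 and 0.02 for Jun and Egr1 with quantile normalization.

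Other rises were those of Tmem14a (597 ± 54 against 36.2 ± 34, 3.89), Zfp37 (2.74), Prkcz (2.62), Mlc1 (2.26), the peroxisomal membrane protein Pxmp4 (5800 ± 410 against 1240 ± 160, 2.21), Dna2 (2.16), Pla2g2d (2.07), Cpa1 (1.97), Gpam (1.22) and the xenobiotic receptor Nr1i3 (1.22). Cyp7a1 rose from 5470 ± 220 to 11900 ± 530 (1.12, SE 0.05, adjusted p = 4.45e-11), and by 0.96, under 2-fold, with centred arrays. Genes that fell were the lipid droplet protein Plin5 (-2.29), the bile acid transporter Slc10a2 (120 ± 32 against 609 ± 64, -2.26), the endothelial transcription factor Sox18 (-2.18), Fgf13 (-1.98), Nkain1 (-1.81), the secreted phospholipase Pla2g2a (-1.8) and the small heat shock protein Hspb7 (-1.75; another probe set -0.28). G6pc1 (0.36), Ccnd1 (0.32) and Igfbp1 (-0.27) stayed under 2-fold. Ppargc1a (0.89), Adra1b (0.23), Alb (-0.13), Hgf (0.12), Tnf (0.13) and Chrm3 (0.48) did not pass the test, nor did Pck1 (0.08, and -0.08 with centred arrays); without PH replicate 3 Tnf was at -0.5, and without PH replicate 1 Chrm3 was at -0.05.

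In TDPH 285 probe sets were higher and 80 lower than in PH (115 and 47 genes), with a median of 0.106 over all tested; the split was 156 and 104 with quantile normalization and 149 and 145 with centred arrays. The falls of S1pr3 and Adra2c and the rise of Clock ended when a single array was left out, with the highest adjusted p at 0.131 (S1pr3 without PH replicate 2), 0.154 (Adra2c without TDPH replicate 3) and 0.147 (Clock without TDPH replicate 1). With a pseudocount of 90 the differences of Plin5, Sox18, Fgf13, Nkain1 and Nr1i3 lay between -1 and 0.95 and were not called.

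The lists of adrenergic and cholinergic receptors and of nerve and Schwann cell markers were not called in any denervated group against PH, with adjusted p of 0.877 and 0.587 in SPH, 0.248 and 0.911 in VPH, and 0.718 and 0.98 in TDPH.

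The direct comparisons tested whether the denervated groups differed from each other. Lymphocyte markers were lower as a list in SPH than in VPH, and immediate early genes were higher. Cxcl9 was at 871 ± 290 in SPH and 5740 ± 210 in VPH (n = 3; log2 difference -2.75, adjusted p = 2.48e-10), and the MHC class II gene RT1-Bb was at 1430 ± 150 against 8520 ± 49 (-2.57, adjusted p = 3.93e-15). Of 20 lymphocyte markers 8 were lower in SPH than in VPH (9 adjusted over the list alone; median -0.86, adjusted p = 0.000103). Cd74 was at 6549, 8276 and 20110 on the SPH arrays, the last close to the VPH arrays (21060 to 21260). Nr4a1 was higher in SPH (8540 ± 1100 against 1770 ± 29, 2.26), as were Bach1 (3.4), Cxcl2 (2.82), Tgfbr2 (2.75) and Rnf152 (2.35). Of 37 immediate early genes 5 were higher in SPH (5 adjusted over the list alone; median 0.3, adjusted p = 2.59e-08), and the cAMP response list had 2 of 18 higher and 1 lower (the same over the list alone; median 0.38, adjusted p = 8.84e-08). Cpa1 (-4.04), Ntf3 (-3.6) and Wnt4 (-2.58) were lower in SPH. In all, 327 probe sets were higher and 286 lower in SPH than in VPH, and 391 were called when only these groups were fitted.

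Neutrophil markers were lower as a list in TDPH than in SPH. The adjusted p of single genes here uses a spread pooled over all groups, while the SPH arrays differed among themselves, at 12100, 7700 and 5440 for S100a8. S100a8 was at 1340 ± 170 in TDPH and 8420 ± 3400 in SPH (n = 3; -2.57, adjusted p = 5.14e-09), and S100a9 at 3730 ± 310 against 19100 ± 7400 (-2.29). Of 9 neutrophil markers 7 were lower in TDPH (8 adjusted over the list alone; median -1.51, adjusted p = 4.67e-09), and the decoy receptor Il1r2 (-2.46), Chi3l1 (-2.23) and Duoxa1 (-2.75) were lower too. Ppp1r3c was at 2160 ± 170 in TDPH against 258 ± 110 in SPH (3.08, adjusted p = 4.49e-10), and the hepatocyte transcription factor Onecut1 at 4670 ± 180 against 767 ± 310 (2.66). Serpinb9b (4.15), Cpa1 (3.79) and Zfp37 (2.92) were higher as well. There were 246 probe sets higher and 120 lower in TDPH than in SPH, or 193 and 146 with quantile normalization and 191 and 166 with centred arrays, and 199 in all when only these groups were fitted.

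Against VPH, TDPH had lower lymphocyte markers (8 of 20, or 9 adjusted over the list alone; median -0.93, adjusted p = 3.96e-05) and a lower macrophage list (1 of 15, the same over the list alone; median -0.57, adjusted p = 1.31e-11). Cxcl9 was at 933 ± 52 in TDPH and 5740 ± 210 in VPH (n = 3; -2.61, adjusted p = 3.96e-10), and Lcn2 at 1150 ± 100 against 6510 ± 55 (-2.49). The MHC class I gene RT1-T24-4 (-2.58), the hemoglobin chaperone Ahsp (-2.59) and the defensin gene RatNP-3b (-2.4) were also lower. Obp3 was higher in TDPH (22500 ± 2700 against 3950 ± 200, 2.5), as were Tmem14a (3.63), Mlc1 (2.68), Bach1 (2.65) and Rnf152 (2.57). In total 430 probe sets were higher and 194 lower, or 338 and 240 with centred arrays and 699 and 363 with array weights.

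The non-additivity contrast asked whether total denervation differed from the sum of the changes after sympathectomy and vagotomy. Neutrophil, lymphocyte and macrophage genes were lower as lists in TDPH than that sum. Of 9 neutrophil markers 7 had a lower value (9 adjusted over the list alone; median -2.07, adjusted p = 6.33e-08), with S100a8 at -2.98 and Cxcr2 at -2.77. Of 20 lymphocyte markers 6 did (9 adjusted over the list alone; median -1.01, adjusted p = 3.23e-06), and of 15 macrophage markers 4 did (4 adjusted over the list alone; median -0.8, adjusted p = 1.18e-19). The largest negative values were those of RT1-T24-4 (-4.26), Pla2g2d (-3.53), Lcn2 (-3.22), Rhoh (-3.17) and Chi3l1 (-3.12). Ubd was at 8690 ± 620 in TDPH, 4130 ± 3300 in SPH, 2170 ± 40 in VPH and 8540 ± 60 in PH (n = 3 each; 3.31, SE 0.4, adjusted p = 1.15e-05). Obp3 (3.21), Wnk2 (3.0) and Bsn (2.93) were also above additivity, and so was a probe set of Dhrs7 (3.76), while another of that gene was at 0.01. Some of these values rest on SPH arrays that differed among themselves, while the SE pools the spread of all groups. The SPH arrays were at 2510, 7870 and 1990 for Ubd, at 3830, 1400 and 895 for RT1-T24-4, and at 3280, 1520 and 1090 for Lcn2. The contrast was positive for 342 probe sets and negative for 413.

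**Figure D3:**
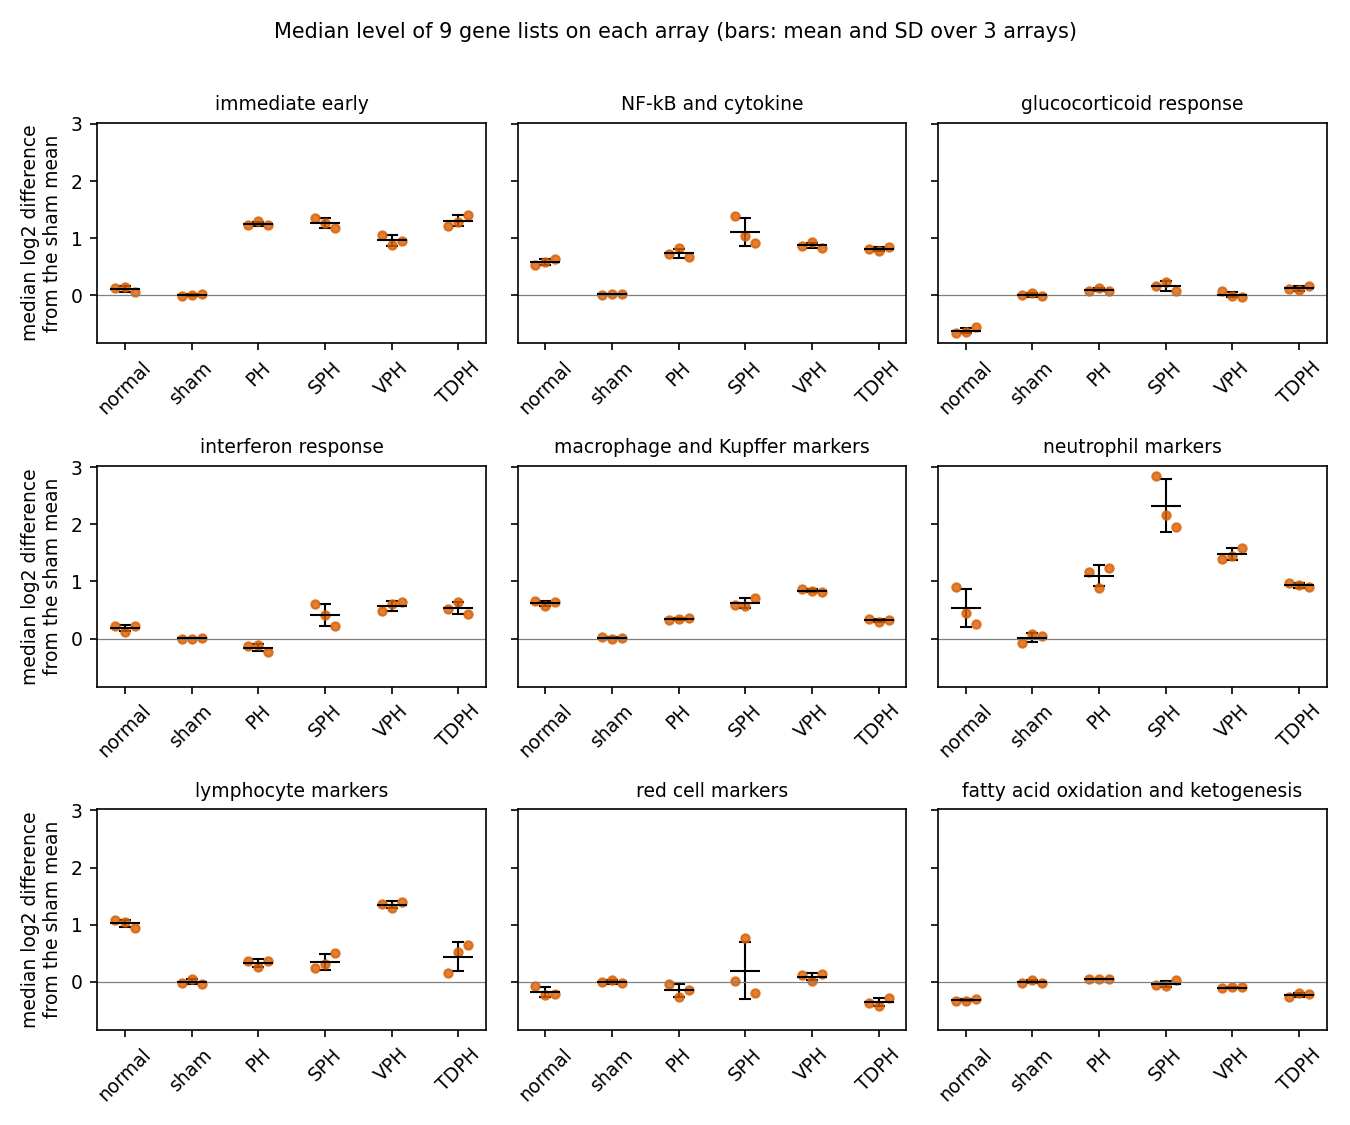
Median level of the members of 9 gene lists on each array, as log2 difference from the mean of the sham arrays (vertical axis), by group, with the mean and SD of 3 arrays; these lists were chosen after their values were seen. Neutrophil markers are at 1.1 ± 0.18 after PH and 2.32 ± 0.46 in SPH, and lymphocyte markers at 1.02 ± 0.07 in normal liver and 1.35 ± 0.06 in VPH.

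The response to PH was also followed in the denervated groups by comparing each with sham operation. The immediate early list was called higher in all 3 denervated groups, with 22 of 37 members higher in SPH (median 1.26), 18 in VPH (median 0.97) and 22 in TDPH (median 1.34), against 21 after PH alone. Of the 438 probe sets raised by PH, 362 (82.6%) were also called higher than sham in SPH, 315 (71.9%) in VPH and 301 (68.7%) in TDPH. Of the 525 lowered by PH, 260 (49.5%) were called lower in SPH, 173 (33%) in VPH and 77 (14.7%) in TDPH. In all, 772 probe sets were lower than sham in SPH, 554 in VPH and 187 in TDPH, of which 512, 381 and 110 were not called lower after PH. Because the 438 and 525 were chosen on the PH arrays, a lower share in the other groups is partly built in.

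Calls shared by the comparisons with PH were counted, since all of them use the same PH arrays. SPH and VPH shared 58 probe sets higher and 18 lower than PH, SPH and TDPH 89 and 19, and VPH and TDPH 74 and 13. Independent lists of these sizes would share 2.3 and 0.8, 2.7 and 0.4, and 3.1 and 0.6. In 100 draws of simulated unchanged groups that shared simulated PH arrays, 0.01 or fewer calls were shared on average. Nothing differed in those draws, so few calls were possible. They cannot show how many shared calls come from the shared PH arrays where groups do differ. Log2 differences correlated across probe sets at r = 0.4, 0.49 and 0.4, against 0.5 in simulated unchanged groups, and their covariances were 0.08, 0.092 and 0.078 against a simulated 0.048. The 3 PH arrays could not be split, so part of the excess of shared calls may come from the shared controls, and with a pseudocount of 90 the shared calls numbered 25, 33 and 26.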

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

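The tests of array scaling by probe sets of the same signal level and of signal level ordering the groups, of the PH RNA or the sham RNA standing alone, of the unmatched VPH column and of the hepatocyte share, and the blood test as divided between sham and VPH, were chosen after the results were seen, as was the rule that picked lists here (adjusted p under 0.05 with an estimated correlation and a median of at least 0.5).

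Differences between the denervated groups, each tested by its own contrast, were called for 613 probe sets between SPH and VPH, 366 between TDPH and SPH and 624 between TDPH and VPH, and the non-additivity contrast was called for 755. By list, lymphocyte markers were lower in SPH than in VPH (median -0.86). Neutrophil (-1.51), stellate (-0.52) and red cell markers (-0.55) were lower in TDPH than in SPH. The red cell level varied between the SPH arrays (0.2, SD 0.51, relative to sham, against SDs of 0.03 to 0.11 in the other groups). Macrophage (-0.57) and lymphocyte markers (-0.93) were lower in TDPH than in VPH. In the non-additivity contrast macrophage (-0.8), neutrophil (-2.07), lymphocyte (-1.01) and red cell markers (-0.63) were below 0.

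Whether such counts could arise from noise between arrays was tested by regrouping them. For each comparison of 3 with 3 arrays, 1 of the 10 splits, the real one, gave as many calls as observed. The highest other counts were 1 (PH with sham, observed 963), 0 (sham with normal, 667), 1 (SPH with PH, 328), 1 (VPH with PH, 397), 0 (TDPH with PH, 365), 3 (SPH with VPH, 613), 2 (TDPH with SPH, 366) and 0 (TDPH with VPH, 624), but 10 splits are too few for a share under 0.05. For the non-additivity contrast 1 of 100 relabellings, the real one, reached 755, and the highest other gave 180, which argues against noise between arrays as the only source. Each relabelling mixes arrays of PH, SPH, VPH and TDPH, which differ from each other, and so widens the spread within the relabelled groups. It therefore cannot tell non-additivity from any other difference among these groups. The labels call the arrays of a group technical replicates, which can resemble each other whatever the cause, so regrouping tests noise between arrays alone and not differences between animals. The SPH arrays resembled each other less than those of the other groups (median SD of log2 signal 0.129 against 0.061 to 0.082).

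The probe sets lowered by PH are the first pattern weighed: 525 were lower than after sham operation, of which 260 were called lower in SPH, 173 in VPH and 77 in TDPH; they were chosen on the PH arrays, are dim (median signal 148 against 259 for all tested) and are often unnamed (41.7% against 29.5%). All tested probe sets at the same signal levels were at -0.12 in PH against sham (SD between arrays 0.07), where the 525 had a median of -1.34. They were 0.13 higher in TDPH than in PH (SD 0.08), where the 525 were 0.74 higher. Choosing the 525 on the PH arrays enlarges both of their values, so these gaps are partly built in. The SPH, VPH and TDPH arrays did not choose the 525. There all tested probe sets at those levels were at -0.07 (SD 0.06), -0.06 (SD 0.01) and 0 (SD 0.04) against sham, and normal liver was at 0.06. The 525 were at -0.92, -0.71 and -0.51 against normal liver, which argues against scaling as the whole cause. All tested probe sets at those levels ran in the same order, as did median signal (131.9 in SPH, 133 in VPH and 139.7 in TDPH). Signal level is therefore argued against as the source of the size of these differences, while their order cannot be told apart from it. The first test of scaling, the percent still called lower under quantile normalization, gave 62.5, between its bounds, so the number of calls depends on the scaling. Signal of single probe sets is argued against by other probe sets of the same genes, 78.8% of which lay below 0 (95% interval 71.6 to 84.8), against 61.8% of all tested. PH RNA standing alone is argued against, for the 525 as a set, by SPH, VPH and TDPH, which did not choose them and lay below normal liver. A median cannot decide it for single probe sets, and 117 of the 525 were called higher in TDPH than in PH. Sham RNA standing alone is argued against by sham, which was chosen as high and still lay near normal liver. Levels relative to normal liver were -1.24 in PH (SD 0.04, chosen as low), -0.92 in SPH (SD 0.06), -0.71 in VPH, -0.51 in TDPH and 0.06 in sham. These levels follow the order of the 3' to 5' Actb ratio in the 2 h groups (1.76, 1.8, 1.84, 2.0 and 2.19), though normal liver, at 1.89, does not and the Gapdh ratio breaks it in VPH (1.21, 1.29, 1.18, 1.3 and 1.35), so RNA integrity stays open as untested, as do the denervation operation itself and a nerve-dependent response to PH.

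The second pattern weighed is that lymphocyte markers were lower as a list in sham than in normal liver (median -1.01) and higher in VPH than in PH (0.95). A smaller amount of blood left in the perfused liver is argued against for the fall in sham, because red cell markers were at 0.17 there. Red cell markers do not measure how many lymphocytes that blood held, so fewer lymphocytes in it stay open as untested. For the rise in VPH red cell markers were at 0.31, and blood cannot be told apart from a change in lymphocytes because that value lies between the bounds. A changed share of hepatocytes would move all other cell types alike, but in VPH the endothelial and stellate lists were at -0.25 each, and in sham the levels of endothelial (-0.36), stellate (-0.37) and cholangiocyte markers (-0.21) were lower by less than that of lymphocyte markers (-1.02), so a higher share there is argued against as the whole cause and stays open for part of the fall. Counting VPH replicates 2 and 3, which resemble each other most (r = 0.977, SD of the log2 difference 0.176, against 0.947 to 0.963 and 0.233 to 0.378 in other groups), as 1 array left the lymphocyte median at 0.91. The number of animals behind each group is not given in the sources used here, so differences between animals stay open as well.

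A signal was found in data outside the comparisons: the first column under the VPH heading of the second deposited table equals no array of the value table, yet correlated with the VPH mean at 0.966, with 0.962 for the PH mean as the next highest. The SD of its log2 difference was 0.234 from the VPH mean and 0.38 from the PH mean, a ratio of 1.62, which argues against an array of another group. Relative to PH its lymphocyte list was at 1.12 (0.89, 0.95 and 1.03 on the VPH arrays), its macrophage list at 0.54 and its interferon response list at 0.53.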

How the results depend on the processing

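Centring the arrays and averaging VPH replicates 2 and 3 were chosen after the results were seen. Among the genes taken by the naming rule in the primary comparisons, no called gene reversed its direction. Reversal was not tested for the other called genes, nor in the direct comparisons or the non-additivity contrast. Under quantile normalization camera's direction, which is relative to the other genes, turned for 7 list results: in PH with sham fatty acid oxidation (median -0.04), urea cycle (-0.05) and hepatocyte secreted genes (-0.01), in sham with normal hepatocyte secreted genes (0.02, the sign kept), and in TDPH with PH urea cycle (0.03), hepatocyte secreted (-0.01, the sign kept) and cholesterol synthesis genes (0.11), the last called there (adjusted p = 0.0418) and the others no longer. The cause was not tested. The median of the ER stress list in VPH with PH also changed sign (0.01), and its call ended. Counts of changed probe sets stayed within 1.5 times under quantile normalization, a pseudocount of 1, no filter, no mean-variance trend, the second table's signals, averaged VPH replicates and centred arrays. In the order PH with sham, sham with normal, SPH, VPH and TDPH with PH, SPH with VPH, TDPH with SPH, TDPH with VPH and non-additivity, a pseudocount of 90 gave 385, 325, 105, 145, 100, 171, 123, 190 and 482, as it shrinks differences of dim probe sets. Adjusted p alone gave 4951, 3713, 3144, 2649, 3932, 4475, 3182, 4658 and 2724, a 3-fold minimum 321, 205, 107, 140, 87, 175, 114, 174 and 284, and the 2-fold rule with no test 1536, 1158, 878, 1058, 848, 1205, 878, 1211 and 2364. Array weights gave 209 (SPH with PH), 678 (VPH with PH) and 1062 (TDPH with VPH), and the cause was not tested. Fitting only the groups compared gave 168 (SPH with PH), 391 (SPH with VPH) and 199 (TDPH with SPH), and 652 for non-additivity. Comparisons without SPH changed less, at 904 (PH with sham), 662 (sham with normal), 346 (VPH with PH), 304 (TDPH with PH) and 609 (TDPH with VPH). The full fit uses a spread common to all groups, while the SPH arrays differed most among themselves (median SD 0.129 against 0.061 to 0.082). That common spread is therefore typically smaller than the spread of the SPH arrays. How many calls in the comparisons with SPH rest on it was not tested.

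Leaving out each array in turn gave 881 to 1013, 604 to 656, 293 to 390, 289 to 445, 303 to 388, 438 to 675, 306 to 476, 518 to 732 and 622 to 820 in the same order. Among the genes taken by the naming rule in the primary comparisons, 14 calls ended without at least 1 of the arrays. With a pseudocount of 90, 23 calls of these genes ended, and 13 ended with only the groups compared. Of the 75 called lists, 29 were called with an estimated correlation, 73 with fry, 59 with quantile normalization, 69 with centred arrays and 73 with the mean of each gene's probe sets. Replicate numbers did not pair arrays across groups (correlations of -0.027 to 0.058 for the same number, 0 of 24 over 0.1); with the number as a block the counts were 963, 654, 320, 397, 366, 597, 371, 618 and 754. A filter on detection calls was not run, because the files hold none. Signal over background limits the dim probe sets, whose log2 differences depend most on the pseudocount.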

Other observations

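The spread between arrays, the probe sets shared by the 3 denervated groups and the genes of growth hormone signaling were examined after the results were seen, while the test of Cish was set before its value was seen.

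Several metabolic and stress lists not described above moved by small amounts in SPH against PH. Genes of ER stress and the amino acid response were higher as a list (1 of 30 rose, the same over the list alone; median 0.19, adjusted p = 1.48e-06), and the gene that rose was Chac1, which degrades glutathione (1.17). Cholesterol synthesis genes were higher (1 of 25 rose, the same over the list alone; median 0.19, adjusted p = 8.37e-09, and adjusted p = 0.0507 with an estimated correlation). Bile acid synthesis and transport genes were higher as a list (median 0.16, adjusted p = 0.000224), and ribosome biogenesis genes were lower (median -0.24, adjusted p = 0.000225), with 20 of 20 and 35 of 35 members not called singly. Circadian clock genes had 1 of 14 higher (1 adjusted over the list alone; median 0.21, adjusted p = 0.00259), namely Clock (1.38). In TDPH against PH the circadian list was also higher (1 of 14, the same over the list alone; median 0.36, adjusted p = 0.00974, and adjusted p = 0.0795 with an estimated correlation).

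All 3 denervated groups had 40 probe sets higher and 7 lower than PH. Of the 40, 25 were called lower in PH than in sham, which the shared PH arrays partly build in: the differences of PH from sham correlated with those of SPH, VPH and TDPH from PH at r = -0.19, -0.32 and -0.47, against -0.5 in simulated unchanged groups. The largest differences were those of a probe set of the MHC class I gene RT1-CE5, at 4.43, 5.56 and 3.96 in SPH, VPH and TDPH against PH and at -4.13 in PH against sham. A second probe set of RT1-CE5 was at 2.85, 3.63 and 2.33 (-2.37 in PH against sham), while the remaining probe set of that gene was at -0.13, -0.21 and -0.03 and was not called. The interferon-induced Mx1 (1.18, 1.46 and 1.79) and Isg15 (1.21, 1.46 and 1.63), the nucleotide receptor P2ry6 (1.88, 2.26 and 1.45) and the mitotic kinesin Kif20a (1.26, 1.25 and 1.16) were among the genes higher in all 3, while another probe set of Kif20a was at -0.85, 0.81 and 0.29. P2ry6 (-1.38) and Kif20a (-1.75) had been lower in PH than in sham. The bile acid transporter Slc10a2 was lower in all 3 (-1.42, -1.43 and -2.26). All of these comparisons share the PH arrays.

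The SPH arrays differed most among themselves: of 7247 probe sets with a mean signal over 500, 178 had an SD of log2 signal above 0.5 in SPH, against 9 to 20 in the other groups, and the median SD was 0.129 against 0.061 to 0.082. Ubd was at 2510, 7870 and 1990 on the 3 SPH arrays, RT1-T24-4 at 3830, 1400 and 895, and Lcn2 at 3280, 1520 and 1090.

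A hypothesis was tested for Socs2 and Onecut1, which both respond to growth hormone and were lower in SPH than in PH (-1.54, adjusted p = 2.68e-07, and -1.47, adjusted p = 2.44e-06, with another Onecut1 probe set at -0.82): growth hormone signal may have differed between the RNA samples. Cish, another target of that hormone through STAT5, should then have been lower too. It was at 0.11 in SPH against PH (95% interval -0.24 to 0.45), so the predicted fall was not seen. That interval uses the spread pooled over all groups, while Cish signal was 2230 ± 830 in SPH and 1980 ± 86 in PH. Cish is also on the IL6-STAT3 list and may respond to other signals, so its value cannot decide the hypothesis. Among the other genes examined, Bcl6 was at -0.72 (adjusted p = 0.00447) and Igfals at -0.08 in SPH against PH. Cish rose in PH against sham (2.06, adjusted p = 1.33e-08), Igf1 was at -0.11 in SPH against PH, and Onecut1 rose in TDPH against PH (1.19, adjusted p = 1.79e-05).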
